A study of Mus musculus with 12 samples.

How the data were processed

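Total RNA from cultured mouse embryonic fibroblasts was labelled with Cy3 and hybridised, per the labels, to Agilent 1-colour miRNA arrays, which the authors read with Agilent Feature Extraction 10.7.1.1. Each array had 13715 spots, of which 13000 were not controls; they made up 1857 probes for 650 miRNA names, 611 of mouse and 39 of mouse viruses. Per the file headers the spot values are intensity in arbitrary units: the processed signal is background-subtracted and spatially detrended, and not scaled between arrays. The total gene signal per miRNA, also an intensity made by the authors' software, is set to 0.1 where a miRNA was not detected. The deposited value table is on a log2 scale: each value equalled the log2 of the total gene signal, with no scaling or centring, and undetected miRNAs are blank. Its columns had medians from 5.44 to 6.90. Other columns deposited by the authors, per the file headers, hold 0 or 1 flags.

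The signal of a miRNA was taken as the sum over its probes of the mean processed signal of the probe's spots, with control spots and spots flagged as outliers left out. It was divided by the array's 75th percentile over the 82 miRNAs well above background on all 12 arrays, raised to a floor of 0.0322 (-4.96 on the log2 scale, the median over arrays of the 1st percentile of scaled signals well above background) and put on a log2 scale. A probe counted as well above background when at least 50 percent of its spots carried that flag, and a miRNA when any probe did. The 145 mouse miRNAs well above background on both arrays of at least 1 group were tested; the others were left out as too dim. Where a group was not well above background, the fold is given as a lower bound. For it, the dim group's values were raised to the lowest level well above background on their array, where that was higher. The bound covers neither the standard error nor other processing. Across the alternatives the log2 difference of miR-196a in untreated KO was as low as 0.34. At 12 h in WT that of miR-146a was as small as -0.60 and that of miR-34c -0.26. On such arrays the signal over background, and so the floor, limits what can be seen.

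The 6 groups of 2 arrays were fitted together in R 4.3.3 with limma 3.58.1 (lmFit on group means, then eBayes), which left 6 residual degrees of freedom with a prior of 1.03; Benjamini-Hochberg adjustment ran over the 145 miRNAs with a threshold of 0.05. There were 9 comparisons: tunicamycin against untreated at 12 h and at 24 h in each genotype, the KO response minus the WT response at each time, KO against WT untreated, and 24 h against 12 h in each genotype. Groups, comparisons, the measure, the miRNA lists and the rule for naming miRNAs were set before the data were examined. The rule named up to 10 miRNAs each way with the largest difference among those past the threshold whose 2 arrays per group did not overlap, up to 5 each way for 24 h against 12 h, and the 5 with the smallest p where fewer than 5 passed; up to 4 members of each list and any member of the list linked to the unfolded protein response could be added.

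Lists were tested with limma's camera (preset correlation 0.01) when at least 3 members were tested, adjusted over the 8 such lists of 16 in each comparison, then with an estimated correlation and with fry. They were the miRNAs tied by earlier work to the unfolded protein response, the miR-17~92 cluster and paralogs, let-7, p53-linked miRNAs, fibroblast-abundant miRNAs (which share 9 tested members with the first list), the miR-466 group (miR-297, miR-466, miR-467 and miR-669), the miR-15/16 clusters with the cluster of miR-322 and miR-503, and star strands. Of the 22 list calls by camera, 0 held with an estimated correlation; fry, which tests whether a list's members move and does not compare them with other miRNAs, called 16 as moving on balance 1 way and 29 in either direction. The other lists had too few tested members: the Dlk1-Dio3 cluster 1, blood and endothelium 1, names linked to tRNA or rRNA fragments 1, and epithelial, muscle, neural, pluripotent and viral lists 0 each. These were the marker lists for other cell types and RNA quality.

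Alternatives covered the background correction (normexp with offset 50), the measure per miRNA, the deposited table, the scaling (median, quantile, 75th percentile over all miRNAs, none), the floor, the filter, the spread estimate, the replicate block, the scan date as a fixed or random block (statmod 1.5.0) and leaving out each array. The fit was tested on simulated data made from these arrays, with 40 miRNAs changed in each of 20 rounds: a log2 change of 1 was called for 58.2 percent of miRNAs in the 12 h KO comparison and 40.7 percent in the 12 h genotype difference, and 3.53 and 4.89 percent of calls fell on unchanged miRNAs. The simulated noise was independent between arrays and miRNAs, with 1 SD per miRNA in every group. In these arrays the pooled SD was 0.13 and 0.15 in the untreated groups and 0.51 to 1.23 in the tunicamycin groups. Deviations of tunicamycin arrays of the same number were also correlated, so these rates need not hold here. Scan dates read from the files split the arrays into 4, untreated replicate 1, untreated replicate 2, tunicamycin replicate 1 and tunicamycin replicate 2, so no scan date held both treatments. For the positions of miRNA genes, 549 of 611 mouse names were matched to the annotation of mouse assembly GRCm38.p6; the coordinates served to find neighbouring genes.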

Results

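Mature miRNA levels were measured in mouse embryonic fibroblasts of the C57BL/6 background, either wild type (WT) or lacking ATF4 (KO), a transcription factor of the endoplasmic reticulum (ER) stress response. Cells were untreated or received 2 ug/mL tunicamycin, a blocker of N-linked glycosylation that causes ER stress, for 12 h or 24 h. The 6 groups had 2 arrays each, described in the labels as independent experiments, and the number of arrays limits the precision. The arrays carried probes for 611 mouse and 39 viral miRNA names, of which 92 to 164 per array were well above background, and 145 mouse miRNAs were tested. The 75th percentile of signal that served for scaling ran from 203.5 (KO at 24 h, replicate 1) to 791.2 (untreated KO, replicate 2). No Atf4 mRNA is measured on this array, so nothing here checks the genotype labels. All 4 untreated arrays lay on 1 slide and all 8 tunicamycin arrays on another, so treatment and slide cannot be told apart, and WT and KO arrays occupied different rows of each slide. The p-values measure the spread between these arrays, taken as equal in all 6 groups. It was not equal: the pooled SD was 0.15 and 0.13 in untreated WT and KO and 0.51 to 1.23 in the tunicamycin groups. Standard errors and p of untreated KO against WT therefore rest mostly on the spread of tunicamycin arrays. Where a group is at the floor, the difference is limited by the floor, and its standard error and p leave out the spread below it. Folds given as "at least" allow for the detection limit only, not for the standard error or other processing. Values below are log2 differences of scaled signal ± standard error (n = 2 per group) with p adjusted over the 145 miRNAs by limma.

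The 12 h response of WT cells asks which miRNAs change under ER stress when ATF4 is present. Most of the miRNAs called were lower. Across the tested miRNAs the WT responses of the 2 replicate numbers correlated at -0.14, so the replicates did not share 1 general response. miR-322, a member of the miR-15/16 seed family, fell by 2.01 ± 0.28 (adjusted p = 0.00271), and miR-210, known as a hypoxia-induced miRNA, fell by 1.72 ± 0.18 (adjusted p = 0.000984). miR-148a (-1.34 ± 0.24), miR-222 (-1.63 ± 0.35), miR-342-3p (-1.61 ± 0.36) and the p53-induced miR-34a (-1.36 ± 0.41, adjusted p = 0.0456) were also lower. Several others were not well above background after treatment: miR-146a, known from innate immune signalling, was at least 6.51-fold lower (adjusted p = 0.0110), miR-34c at least 3.71-fold (adjusted p = 0.000984), miR-146b at least 3.12-fold (adjusted p = 0.00774) and miR-34b-5p at least 2.63-fold (adjusted p = 0.00900). The single increase past the threshold was miR-365, at 0.82 ± 0.22 (adjusted p = 0.0304). The miR-34a call was lost without any 1 array other than the KO 24 h arrays and was made in 7 of 23 alternatives. That of miR-365 was lost in 7 of 12 omissions of 1 array (as low as 0.55), all but those of WT 12 h replicate 2 and the KO tunicamycin arrays, and was made in 11 of 23 alternatives. Without untreated WT replicate 1 those of miR-146a, miR-146b, miR-222, miR-342-3p and miR-34b-5p were lost. Without untreated WT replicate 2 those of miR-146a, miR-342-3p and miR-34b-5p were lost, and without WT 12 h replicate 2 those of miR-146a, miR-222 and miR-342-3p. miR-148a turned to 0.57 with the Agilent total gene signal and 0.35 with the deposited table.

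Of the 6 tested members of the miR-15/16 and miR-322 clusters, 5 were lower and 1 did not pass (6 lower when adjusted over the list alone), among them miR-16 (-0.94 ± 0.12), miR-15a (-0.82 ± 0.23) and miR-497, at least 2.05-fold lower. The camera test of this list gave adjusted p = 0.00190, and adjusted p = 0.148 with an estimated correlation. Of 6 miRNAs linked to p53, 5 were lower and 1 did not pass (5 lower adjusted over the list alone), including miR-107 (-0.80 ± 0.14) and miR-143 (-1.19 ± 0.21). Camera gave adjusted p = 0.0472, and adjusted p = 0.148 with an estimated correlation. Among 19 miRNAs tied by earlier work to the unfolded protein response, 8 were lower and 11 did not pass (9 lower adjusted over the list alone), such as miR-93 (-0.84 ± 0.15), miR-106b (-0.97 ± 0.16) and miR-25 (-0.74 ± 0.17), with adjusted p = 0.445. Of 30 fibroblast-abundant miRNAs 10 were lower (12 adjusted over the list alone), miR-21 at -1.06 ± 0.19 among them, with adjusted p = 0.722. Of 9 let-7 members 3 were lower (3 adjusted over the list alone), as let-7i at -1.02 ± 0.29, and of 10 miR-17~92 members and paralogs 3 (3 adjusted over the list alone), with adjusted p = 0.445 for both. The miR-466 group (miR-297, miR-466, miR-467 and miR-669, which are alike in sequence) had 3 of 16 lower (3 adjusted over the list alone), although its median was 0.69 and camera placed it higher (adjusted p = 0.0460, and adjusted p = 0.745 with an estimated correlation). Its median differed by 3.87 between the replicates of this group. Of 11 star strands 1 was lower (0 adjusted over the list alone), with a median of 0.03 and camera direction higher (adjusted p = 0.0472, and adjusted p = 0.148 with an estimated correlation).

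In all, 45 of 145 miRNAs passed in the 12 h WT comparison, 1 higher and 44 lower, around a median of all tested miRNAs of -0.32. Relative to that median miR-322 stood at -1.70 and miR-34c at -1.60, and 26 of the 45 calls lay more than 0.5 beyond it. The count rests on the scaling: 0 higher and 3 lower passed with median scaling, 0 and 5 with quantile normalization, 0 and 0 with the 75th percentile over all miRNAs, and 0 and 36 with no scaling. It was 19 without untreated WT replicate 1, 25 without untreated WT replicate 2 and 25 without WT 12 h replicate 2.

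**Figure D1:**
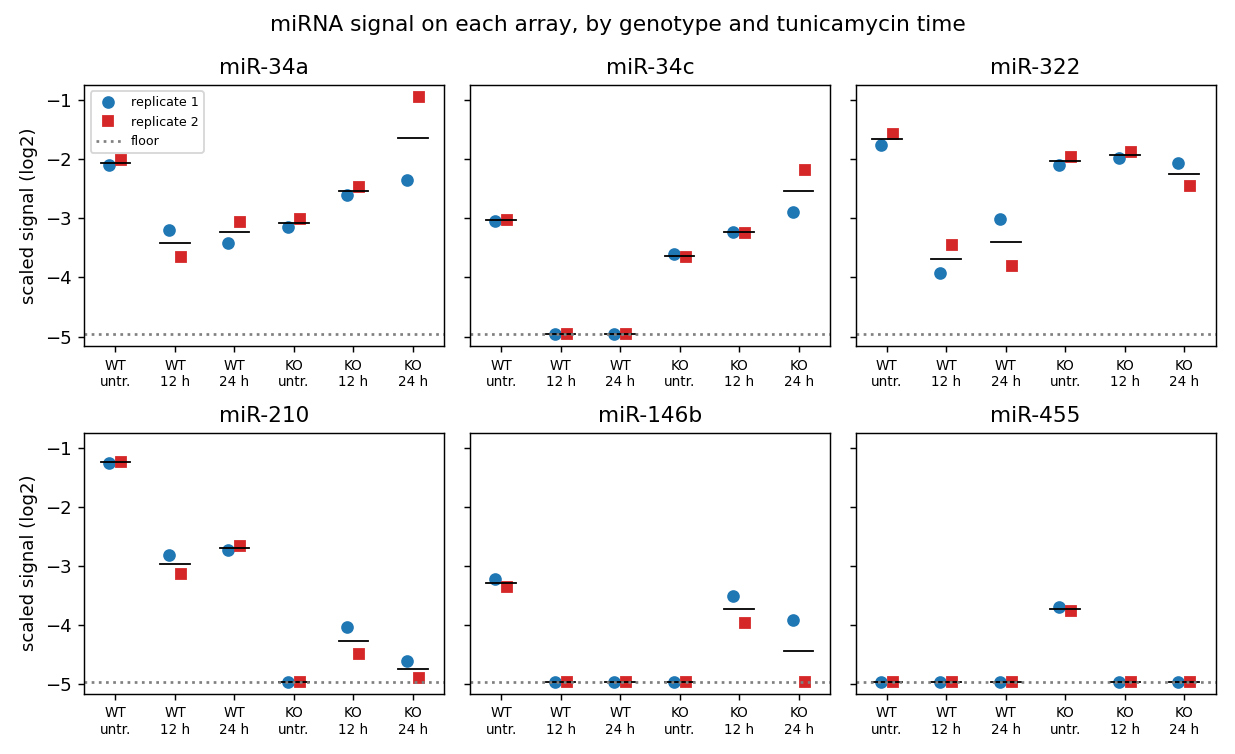
Scaled signal (log2, vertical axis) of miR-34a, miR-34c, miR-322, miR-210, miR-146b and miR-455 on each array by group (horizontal axis), with replicate 1 as circles, replicate 2 as squares, group means as bars and the floor of -4.96 as a dotted line. miR-34c lies at the floor on all 4 WT tunicamycin arrays, and its rise in KO at 24 h turns to -0.05 with no scaling.

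At 24 h in WT cells the same question gave a smaller set, all lower. miR-322 fell by 1.73 ± 0.28 (adjusted p = 0.00816), miR-210 fell by 1.44 ± 0.18 (adjusted p = 0.00314) and miR-26a, an abundant fibroblast miRNA, fell by 1.18 ± 0.15 (adjusted p = 0.00333). miR-143, known from smooth muscle and mesenchymal cells, was at -1.23 ± 0.21, miR-148a at -1.25 ± 0.24 and miR-222 at -1.44 ± 0.35. Not well above background after treatment, miR-34c was at least 2.87-fold lower (adjusted p = 0.00116), miR-146b at least 2.42-fold (adjusted p = 0.0134), miR-34b-5p at least 2.04-fold (adjusted p = 0.0135) and miR-497 at least 1.58-fold (adjusted p = 7.66e-05). All groups but untreated WT were at the floor for miR-497, so its p does not measure the spread of replicates there. With the total gene signal and the deposited table miR-143 turned to 2.29 and 1.54, and miR-148a to 1.19 and 0.44. Normexp turned 9 of these 10 miRNAs, all but miR-210, to an increase. Here and below, a few spots of extreme local background set this fit on WT 24 h replicate 2 and untreated KO replicate 1. The calls of miR-146b, miR-34b-5p and miR-148a were lost without any 1 of the untreated WT or WT 24 h arrays. That of miR-222 was lost without untreated WT replicate 1 or 2, WT 24 h replicate 2 or either KO 12 h array, that of miR-143 without untreated WT replicate 1 or WT 24 h replicate 2, and that of miR-322 without untreated WT replicate 2.

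Of 6 miR-15/16 and miR-322 members, 4 were lower at 24 h in WT and 2 did not pass (5 lower adjusted over the list alone), with miR-16 at -0.72 ± 0.12. Camera gave adjusted p = 0.00175, and adjusted p = 0.194 with an estimated correlation. Of 6 p53-linked miRNAs 4 were lower (5 adjusted over the list alone), with adjusted p = 0.0747. The lists linked to the unfolded protein response (4 of 19 lower, 4 adjusted over the list alone, adjusted p = 0.555), fibroblast-abundant miRNAs (5 of 30, 6 adjusted over the list alone, adjusted p = 0.761), miR-17~92 (2 of 10, 2 adjusted over the list alone, adjusted p = 0.412), let-7 (0 of 9, 0 adjusted over the list alone, adjusted p = 0.550), the miR-466 group (2 of 16, 2 adjusted over the list alone, adjusted p = 0.230) and star strands (0 of 11, 0 adjusted over the list alone, adjusted p = 0.157) did not pass camera. All 22 miRNAs lower at 24 h were also lower at 12 h. These sets are not independent, since both comparisons share the untreated arrays and the tunicamycin arrays share a slide and, by replicate, a scan date. The floor also forces agreement: miR-34c (-1.92), miR-146b (-1.67) and miR-34b-5p (-1.43) were at the floor on all WT tunicamycin arrays, so both times have the same value. Their smaller "at least" folds at 24 h reflect detection limits and not a smaller fall. Of the 22 calls, 9 had a group with no array well above background.

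The 22 calls lay around a median of -0.17 in the 24 h WT comparison, 17 of them more than 0.5 beyond it. Median scaling gave 0 higher and 3 lower, quantile normalization 0 and 4, the 75th percentile over all miRNAs 0 and 0, and no scaling 0 and 63. The count was 10 and 12 without untreated WT replicates 1 and 2, 13 and 7 without WT 24 h replicates 1 and 2, and 47 without either KO 24 h array.

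In KO cells at 12 h, miR-455 was lower than in untreated KO cells (adjusted p = 3.88e-05), with both treated arrays at the floor, which limits its value of -1.23 ± 0.06. All groups but untreated KO were at the floor for miR-455, so this error and p do not measure the spread of replicates there. Normexp fitted without spots of outlying local background turned it to 0.07. It is encoded in an intron of the collagen gene Col27a1. It was the single miRNA past the threshold. The next smallest p belonged to miR-24-1* (-0.51 ± 0.09, adjusted p = 0.0503), miR-24 (-0.35 ± 0.08) and the cholesterol-linked miR-33 (-0.59 ± 0.14), both with adjusted p = 0.131, and miR-146b (1.23 ± 0.31, adjusted p = 0.143). The floor limits miR-24-1* and miR-33 on treated arrays and miR-146b on untreated ones. In the list linked to the unfolded protein response 1 of 19 was lower (3 adjusted over the list alone), with a list median of -0.28. Camera gave adjusted p = 0.000113, and adjusted p = 0.329 with an estimated correlation. Let-7 members had 0 of 9 past the threshold (0 adjusted over the list alone) but a median of 0.33, with camera adjusted p = 0.00203 and adjusted p = 0.329 with an estimated correlation. Fibroblast-abundant miRNAs had 0 of 30 (2 lower adjusted over the list alone) with camera direction lower (adjusted p = 0.00109, and adjusted p = 0.329 with an estimated correlation). The miR-466 group had 0 of 16 (0 adjusted over the list alone) with a median of 1.26, which differed by 3.58 between replicates (adjusted p = 0.0503). The miR-17~92 (0 of 10, 0 adjusted over the list alone, adjusted p = 0.146), p53-linked (0 of 6, 0 adjusted over the list alone, adjusted p = 0.362), miR-15/16 (0 of 6, 0 adjusted over the list alone, adjusted p = 0.837) and star-strand (0 of 11, 1 lower adjusted over the list alone, adjusted p = 0.145) lists did not pass. The median of all miRNAs was 0.06. Median scaling, quantile normalization and the 75th percentile over all miRNAs each gave 0 higher and 1 lower, no scaling gave 0 and 19, and 14 passed without either KO 24 h array.

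At 24 h in KO cells miR-34c rose by 1.09 ± 0.20 and let-7b, of the let-7 family of growth-restraining miRNAs, by 0.71 ± 0.13 (adjusted p = 0.0410 for both). With no scaling these values were -0.05 and -0.44, and let-7b was at -0.16 with the 75th percentile over all miRNAs and -0.44 with the deposited table. Normexp gave -0.22 for miR-34c. Each of these 2 calls was lost without any 1 array other than the KO 24 h arrays, and that of let-7b also without KO 24 h replicate 2. miR-455 was at least 1.80-fold lower (adjusted p = 3.88e-05), but turned to 0.39 with normexp fitted without spots of outlying local background. miR-34b-5p (1.23 ± 0.28, adjusted p = 0.0710) and miR-24-1* (-0.45 ± 0.09, adjusted p = 0.0507) did not pass. Let-7 members had 1 of 9 higher (3 adjusted over the list alone) and a median of 0.35. Camera gave adjusted p = 0.00237, and adjusted p = 0.444 with an estimated correlation, and its direction turned with no scaling. The list linked to the unfolded protein response had 1 of 19 lower (3 adjusted over the list alone; camera adjusted p = 0.0182, and adjusted p = 0.444 with an estimated correlation). Fibroblast-abundant miRNAs had 0 of 30 (1 lower adjusted over the list alone), with a median of -0.22, camera adjusted p = 0.000120 and adjusted p = 0.444 with an estimated correlation. Of 6 p53-linked miRNAs 1 was higher (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.330). The miR-17~92 (0 of 10, 0 adjusted over the list alone), miR-466 (0 of 16, 0 adjusted over the list alone), miR-15/16 (0 of 6, 0 adjusted over the list alone) and star-strand (0 of 11, 1 lower adjusted over the list alone) lists had adjusted p of 0.440, 0.440, 0.330 and 0.418.

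The 24 h KO comparison had 3 calls around a median of 0.20, relative to which miR-34c stood at 0.89 and let-7b at 0.51. Median scaling, quantile normalization and the 75th percentile over all miRNAs each gave 0 higher and 1 lower, and no scaling 0 and 55. The count was 37 without KO 24 h replicate 1, 11 without KO 24 h replicate 2, and 1 without any other single array. By limma 0 miRNAs were called in the same direction in WT and KO at the same time, where KO had 1 and 3 calls (21 and 26 at an unadjusted p below the threshold) at 12 h and 24 h. It was 7 with the deposited table, and 50 with no scaling, where the medians of all miRNAs at 24 h were -0.93 in WT and -0.76 in KO. It was 35 with no tunicamycin arrays of replicate 2, where the spread comes from the untreated arrays alone. A count of 0 does not show that WT and KO share no response.

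The study's stated question was which 12 h responses depend on ATF4, tested here as the KO response minus the WT response. Most of the calls were positive. The untreated arrays enter this difference, and that at 24 h, with the opposite sign to KO against WT untreated. These comparisons are therefore not independent, and their medians were 0.49 at 12 h and -0.49 untreated. For miR-146a and miR-455, at the floor in all but 1 of the groups compared, the value is the untreated genotype difference with its sign changed. miR-322 differed by 2.12 ± 0.40 (adjusted p = 0.0147), from a WT response of -2.01 and a KO response of 0.10, and miR-34c by 2.31 ± 0.28 (adjusted p = 0.00199). miR-148a (2.04 ± 0.34), miR-34b-5p (1.97 ± 0.39), miR-129-3p (1.93 ± 0.46), let-7i (1.58 ± 0.41) and miR-26b (1.36 ± 0.23) differed the same way. So did miR-146b (2.90 ± 0.44), miR-146a (2.73 ± 0.78) and miR-210 (2.42 ± 0.25), but these were already at the floor in untreated KO cells, where no decrease could be seen. Lower in the difference were miR-455 (-1.23 ± 0.09), at the floor in every WT group, miR-221 (-1.06 ± 0.30) and miR-24-1* (-0.56 ± 0.13), at the floor in untreated WT cells. With the total gene signal and the deposited table miR-129-3p turned to -2.46 and -2.88, and with the deposited table miR-148a turned to -0.30 and miR-24-1* to 1.86. miR-455 turned to 0.07 with normexp fitted without spots of outlying local background. Normexp turned 8 of the 10 higher miRNAs, all but miR-322 and let-7i, negative. The let-7i call was lost without any 1 array other than the KO 24 h arrays, and that of miR-221 in 9 of 12 omissions (-1.32 to -0.79), all but those of WT 12 h replicate 2 and the KO 24 h arrays, with a call in 6 of 23 alternatives. That of miR-146a was lost in 8 omissions, all but those of the 24 h arrays. That of miR-129-3p was lost in 7, all but those of WT 12 h replicate 1 and the 24 h arrays. Without untreated KO replicate 1 or KO 12 h replicate 2 those of miR-322, miR-34b-5p and miR-24-1* were lost, that of miR-34b-5p also without untreated WT replicate 2, and that of miR-24-1* also without untreated KO replicate 2 or WT 12 h replicate 1.

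Of 6 miR-15/16 and miR-322 members 4 were higher in this 12 h difference and 2 did not pass (5 higher adjusted over the list alone), with miR-16 at 0.99 ± 0.17. Camera gave adjusted p = 0.00332, and adjusted p = 0.117 with an estimated correlation. miR-195 and miR-497 are counted here although both were at the floor in every KO group. Of 6 p53-linked miRNAs 3 were higher (4 adjusted over the list alone), miR-107 at 0.90 ± 0.19 (camera adjusted p = 0.0451, and adjusted p = 0.144 with an estimated correlation). Of 9 let-7 members 4 were higher (6 adjusted over the list alone), let-7g at 1.02 ± 0.22 (adjusted p = 0.0451, and adjusted p = 0.583 with an estimated correlation). The list linked to the unfolded protein response had 3 higher and 3 lower of 19 (4 and 3 adjusted over the list alone, adjusted p = 0.111). The higher were miR-322, miR-25 (0.88 ± 0.24) and miR-106b (1.14 ± 0.22). Fibroblast-abundant miRNAs had 5 higher and 2 lower of 30 (5 and 2 adjusted over the list alone, adjusted p = 0.151), miR-17~92 2 higher of 10 (2 adjusted over the list alone, adjusted p = 0.151) and the miR-466 group 2 higher of 16 (1 adjusted over the list alone, adjusted p = 0.562). Star strands had 1 of 11 lower (1 adjusted over the list alone) and a median of 0, with camera direction lower (adjusted p = 0.0193, and adjusted p = 0.117 with an estimated correlation).

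In the 12 h difference 33 miRNAs passed, 30 higher and 3 lower, around a median of 0.49. Of these, 18 lay more than 0.5 beyond the median. In 7 of the 33 KO was at the floor before treatment and in 21 no group of this comparison was. Median scaling gave 2 higher and 1 lower, quantile normalization 1 and 1, the 75th percentile over all miRNAs 0 and 0, and no scaling 9 and 4. The count was 19 without either untreated WT array, 20 without WT 12 h replicate 2, 10 and 18 without untreated KO replicates 1 and 2, and 11 without KO 12 h replicate 2.

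**Figure D2:**
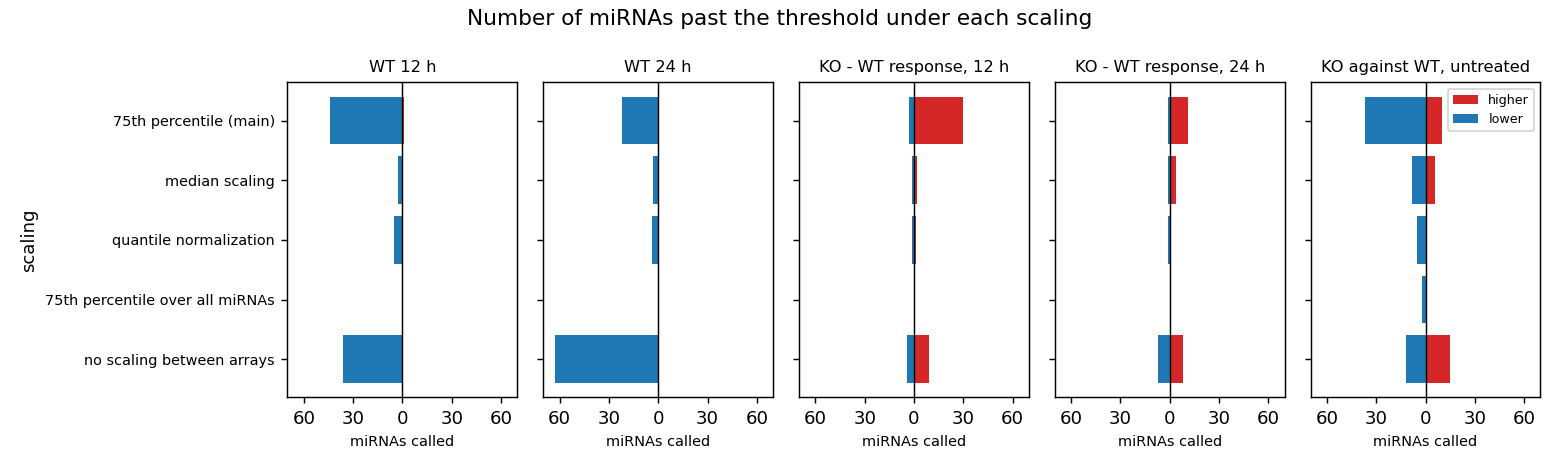
Number of miRNAs past the threshold (horizontal axis, higher to the right in red, lower to the left in blue) under each of 5 scalings (vertical axis) in 5 comparisons, 1 per panel. The 45 calls at 12 h in WT become 3 with median scaling and 36 with no scaling.

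At 24 h the genotypes differed most in the miR-34 family, p53-induced miRNAs that restrain the cell cycle. The KO response minus the WT response was 3.01 ± 0.28 for miR-34c (adjusted p = 0.000586), 2.65 ± 0.39 for miR-34b-5p (adjusted p = 0.00739) and 2.60 ± 0.59 for miR-34a (adjusted p = 0.0430), positive under each of 5 scalings, though with normexp background correction they were -0.88, -1.24 and -0.17. The miR-34a call, with values from 1.90 to 3.30, and those of miR-26a and miR-130a were lost without any 1 array other than the KO 24 h arrays. They were made in 9, 8 and 9 of 23 alternatives. Those of miR-148a and miR-146b were lost in 8 of 12 omissions, for miR-148a all but those of the WT 12 h and KO 24 h arrays and for miR-146b all but those of the KO tunicamycin arrays. miR-148a (1.53 ± 0.34), miR-26a (0.97 ± 0.22) and miR-130a (0.81 ± 0.19) were higher as well, the last pair turning to -0.09 and -0.26 with the 75th percentile over all miRNAs. miR-146b (2.20 ± 0.44) and miR-210 (1.66 ± 0.25) were higher from an untreated KO level at the floor. For miR-497 (1.07 ± 0.09) and miR-195 (0.89 ± 0.09) KO stayed at the floor at 24 h too. Their difference is the WT decrease alone, and no KO decrease could be seen. All groups but untreated WT were at the floor for both, so these errors do not measure the spread of replicates there. miR-455 was lower (-1.23 ± 0.09) with WT at the floor, and turned to 0.11 with normexp fitted without spots of outlying local background. Normexp turned 9 of the 10 higher miRNAs, all but miR-130a, negative.

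Of 6 p53-linked miRNAs 3 were higher in the 24 h difference, the miR-34 members, and 3 did not pass (4 higher adjusted over the list alone; camera adjusted p = 0.0310, and adjusted p = 0.136 with an estimated correlation). Of 6 miR-15/16 and miR-322 members 2 were higher (4 adjusted over the list alone; camera adjusted p = 0.0195, and adjusted p = 0.136 with an estimated correlation). The higher 2 were miR-195 and miR-497, both at the floor in KO untreated and at 24 h, where no decrease could be seen. miR-322 was at 1.51 ± 0.40 (adjusted p = 0.0627). Fibroblast-abundant miRNAs had 1 of 30 higher (0 adjusted over the list alone) and a positive median of 0.10 but camera direction lower (adjusted p = 0.0310, and adjusted p = 0.531 with an estimated correlation), as had star strands with 0 of 11 (0 adjusted over the list alone), a median of 0.11, adjusted p = 0.0310 and adjusted p = 0.136 with an estimated correlation. The list linked to the unfolded protein response had 1 higher and 1 lower of 19 (4 and 3 adjusted over the list alone, adjusted p = 0.123), let-7 1 higher of 9 (3 adjusted over the list alone, adjusted p = 0.108), miR-17~92 0 of 10 (0 adjusted over the list alone, adjusted p = 0.791) and the miR-466 group 0 of 16 (0 adjusted over the list alone, adjusted p = 0.493).

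In the 24 h difference 12 miRNAs passed, 11 higher and 1 lower, around a median of 0.34. Of these, 10 lay more than 0.5 beyond the median. In 4 of the 12 KO was at the floor before treatment and in 5 no group of this comparison was. Median scaling gave 4 higher and 1 lower, quantile normalization 1 and 1, the 75th percentile over all miRNAs 0 and 0, and no scaling 8 and 7. The count was 7 without either untreated WT array, 6 without WT 24 h replicate 2, 6 and 7 without untreated KO replicates 1 and 2, 7 without either KO 12 h array, and 35 and 33 without KO 24 h replicates 1 and 2.

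Untreated KO cells were compared with untreated WT cells for the effect of genotype without stress. miR-210 was lower in KO (adjusted p = 1.94e-05), with both KO arrays at the floor, which limits its value of -3.71 ± 0.18. The immune-linked miR-155 (-2.68 ± 0.26), miR-7a (-2.19 ± 0.22), miR-222 (-2.20 ± 0.35) and miR-129-3p (-2.20 ± 0.33) were lower, as were miR-29b (-1.36 ± 0.27), miR-29a (-1.19 ± 0.29) and miR-29c (-1.08 ± 0.29), known regulators of collagen, and miR-146a was at least 6.66-fold lower (adjusted p = 0.0110). Higher in KO were miR-199a-5p (2.43 ± 0.37), miR-199a-3p (1.20 ± 0.35) and miR-214 (1.81 ± 0.49), which share a host transcript in mesenchymal cells, and the Hox-cluster miR-196a, at least 6.91-fold (adjusted p = 0.0102). miR-27b (1.07 ± 0.28), miR-218 (1.02 ± 0.26), miR-27a (0.76 ± 0.19), miR-33 (0.58 ± 0.14, with 1 WT array at the floor) and miR-24-1* (0.55 ± 0.09, with both WT arrays at the floor, which limits it) were also higher, and miR-455 at least 2.35-fold. Directions turned with the total gene signal and the deposited table for miR-7a (4.25 and 4.59), miR-129-3p (1.82 and 2.16), miR-218 (-2.96 and -2.62) and miR-24-1* (-2.37 and -2.03). Normexp turned miR-146a, miR-155, miR-129-3p, miR-222, miR-7a and miR-29c to an increase. When it was fitted without spots of outlying local background, miR-218, miR-33 and miR-24-1* became 0. The calls of miR-196a, miR-214, miR-199a-3p, miR-27b, miR-218, miR-27a, miR-33, miR-146a, miR-29a, miR-29b and miR-29c were lost without any 1 untreated array, that of miR-199a-3p also without either KO 12 h array, and that of miR-222 without untreated WT replicate 1.

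Fibroblast-abundant miRNAs went both ways in untreated KO, with 7 higher, 10 lower and 13 not past the threshold of 30 (8 and 12 adjusted over the list alone, camera adjusted p = 0.113), and so did the list linked to the unfolded protein response, with 4 higher and 6 lower of 19 (4 and 8 adjusted over the list alone, adjusted p = 0.347). Of 6 miR-15/16 and miR-322 members 3 were lower (4 adjusted over the list alone, adjusted p = 0.0649), as miR-16 at -0.78 ± 0.12. Of 6 p53-linked 2 were lower (3 adjusted over the list alone, adjusted p = 0.670), of 10 miR-17~92 members 2 (0 adjusted over the list alone, adjusted p = 0.189), of 9 let-7 members 1 (1 adjusted over the list alone, adjusted p = 0.347), of 16 in the miR-466 group 2 (2 adjusted over the list alone, adjusted p = 0.788), and of 11 star strands 1 was higher (1 adjusted over the list alone, adjusted p = 0.154).

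In this untreated comparison 47 miRNAs passed, 10 higher and 37 lower, around a median of -0.49, relative to which miR-210 stood at -3.22 and miR-199a-5p at 2.92. Only 21 of the 47 calls lay more than 0.5 beyond that median, so many sat close to the general shift. Median scaling gave 6 higher and 8 lower, quantile normalization 1 and 5, the 75th percentile over all miRNAs 1 and 2, and no scaling 15 and 12. The count was 12 and 21 without untreated WT replicates 1 and 2, 13 without either untreated KO array and 74 without either KO 24 h array.

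The change from 12 h to 24 h of tunicamycin was tested within each genotype. By limma 0 miRNAs passed in WT and 0 in KO, with 5 and 10 at an unadjusted p below the threshold. The smallest p in WT belonged to miR-500 (0.27 ± 0.09), miR-125a-5p (0.35 ± 0.12), miR-720 (0.41 ± 0.15), let-7e (0.35 ± 0.13) and let-7c (0.26 ± 0.10), each with adjusted p = 1. In KO they belonged to miR-96 (0.43 ± 0.12), miR-34c (0.70 ± 0.20), miR-140 (0.91 ± 0.29), miR-152 (-0.36 ± 0.12) and let-7e (0.38 ± 0.13), each with adjusted p = 0.478. In WT the let-7 list had a median of 0.34 with 0 of 9 past the threshold (0 adjusted over the list alone; camera adjusted p = 2.44e-05, and adjusted p = 0.534 with an estimated correlation), a direction that turned with no scaling, and the miR-466 group had camera direction lower against a median of 0.04 (adjusted p = 0.0132, and adjusted p = 0.765 with an estimated correlation). In KO the miR-17~92 list had a median of 0.74 with 0 of 10 past the threshold (0 adjusted over the list alone; camera adjusted p = 0.0360, and adjusted p = 0.604 with an estimated correlation). The other lists had 0 members past the threshold and did not pass camera. Around medians of 0.16 in WT and 0 in KO, no scaling gave 6 lower in KO, and 35 miRNAs passed in KO without KO 24 h replicate 1 and 1 without KO 12 h replicate 1.

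Arrays also stood apart by experiment. Across miRNAs the untreated replicates correlated at 0.995 (WT) and 0.996 (KO), while the WT and KO replicates correlated at 0.685 and 0.750 at 12 h and at 0.941 and 0.799 at 24 h. The tunicamycin responses of the 2 replicate numbers correlated at -0.14 (WT) and -0.02 (KO) at 12 h and at 0.71 and 0.11 at 24 h. miRNAs are not independent replicates. In all 4 tunicamycin groups the miR-466 group was higher in replicate 2, by 3.87 and 0.94 in WT and by 3.58 and 1.80 in KO at 12 h and 24 h, against -0.42 and -0.29 in the untreated groups.

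**Figure D3:**
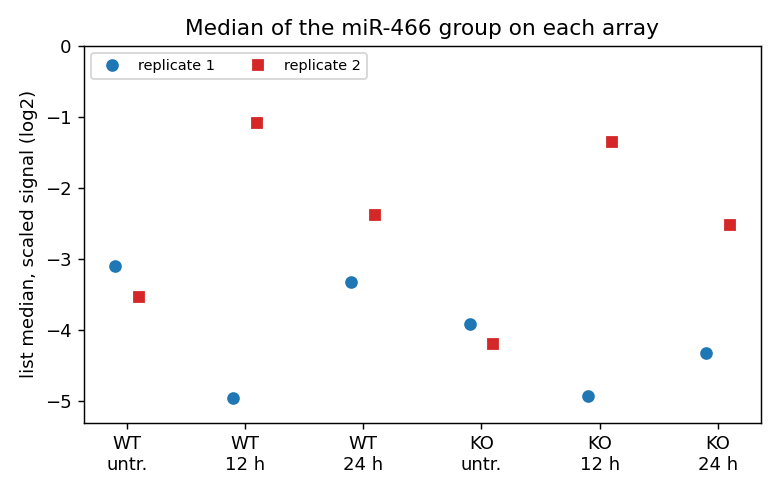
Median scaled signal (log2, vertical axis) of the 16 tested miR-466 group miRNAs on each array by group (horizontal axis), with replicate 1 as circles and replicate 2 as squares. In the 4 tunicamycin groups replicate 2 lies above replicate 1.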

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

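The tests of brightness, of the list median by experiment, of a global loss, of median scaling and of the floor were chosen only after the result was seen; those of spike-in scaling and of a miR-34 difference in 1 experiment alone were set before.

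In the 12 h genotype difference 33 miRNAs passed the interaction test, which is what set them apart here: the KO response minus the WT response was 2.90 for miR-146b, 2.73 for miR-146a, 2.42 for miR-210, 2.31 for miR-34c, 2.12 for miR-322, 2.04 for miR-148a, 1.97 for miR-34b-5p, 1.93 for miR-129-3p, 1.58 for let-7i, 1.36 for miR-26b, -1.23 for miR-455, -1.06 for miR-221 and -0.56 for miR-24-1* (log2). At 24 h 12 passed, with 3.01 for miR-34c, 2.65 for miR-34b-5p, 2.60 for miR-34a, 2.20 for miR-146b, 1.66 for miR-210, 1.53 for miR-148a, 1.07 for miR-497, 0.97 for miR-26a, 0.89 for miR-195, 0.81 for miR-130a and -1.23 for miR-455. Median scaling gave 2 higher and 1 lower at 12 h and 4 and 1 at 24 h, and no scaling gave 9 and 4 at 12 h and 8 and 7 at 24 h. A pair of probes for a mouse cytomegalovirus miRNA, outside the tested set, rose above background on 1 tunicamycin array and on 0 untreated arrays, with scaled signals of 0.0677 (mcmv-miR-M23-1-3p) and 0.0397 (mcmv-miR-M23-1-5p).

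The miR-34 family differed between genotypes at 24 h. For miR-34c, scaling to the 75th percentile as the whole cause is argued against by median scaling, under which it still differed by 2.60 and passed. That test did not cover miR-34b-5p and miR-34a. However, only 1 miRNA passed as higher with quantile normalization and 0 passed with the 75th percentile over all miRNAs. The lowest of the 6 differences over both replicate numbers was 2.10. This cannot decide on 1 experiment alone, since the miRNAs were picked by a test whose error includes the spread between those same arrays. All 12 calls of this difference had the same sign in both replicate numbers. The floor for miR-34a is argued against by its signal, well above background on all 12 arrays and at least 1.31 over the floor. Its call was lost in 10 of 12 omissions of 1 array, however. For miR-34b-5p and miR-34c, at the floor in WT at 24 h, the floor is argued against by differences of 2.25 and 2.61 with those WT values raised to the lowest level well above background. Normexp turned the 3 values negative, but a few spots of extreme local background set that fit. Fitted without those spots, normexp left the 3 values positive, yet none of them passed, so background correction stays open. Slide row, which goes with genotype, stays open too. A biological difference between genotypes is untested beyond this and remains a hypothesis.

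The tunicamycin arrays of replicate 2 stood apart from those of replicate 1. The miR-466 group median was higher in replicate 2 in 4 of 4 tunicamycin groups, which is the pattern itself and does not test a difference between the 2 experiments or scan dates, so this explanation stays open. Overall brightness is argued against, since replicate 2 was brighter in 3 groups and dimmer in KO at 12 h. The labelling spike-in signal (log2) of replicates 1 and 2 was 6.67 and 9.67 in WT and 6.47 and 10.21 in KO at 12 h. At 24 h it was 6.47 and 7.19 in WT and 7.05 and 6.93 in KO. A difference in labelling was not tested as a cause. Experiment and scan date cannot be separated, and no biological explanation was tested.

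The calls at 12 h in WT went mostly 1 way, with 44 of 45 lower. With labelling spike-in scaling the median of all tested miRNAs was -1.42, which by the bound set in advance would argue against the 75th percentile as cause, but that bound was wrong for these arrays, because spike-in signals of replicates differed by up to 3.74 (log2). A global loss of labelled miRNA predicts dimmer raw signal in both WT 12 h arrays, and 1 of 2 was dimmer than both untreated WT arrays. The scaling and a global loss cannot be told apart from these values, as slide goes with treatment.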

How the results depend on the processing

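Tests with median scaling, normexp fitted without spots of outlying local background, the sum of probe totals, the median over spots, the tunicamycin arrays of 1 replicate left out, quantile normalization with the scan date, and the crossed block were chosen only after seeing the data. Of 69 named values past the threshold, 68 kept direction and call with an intensity trend, 68 with the scan date as a random block and 64 with it as a fixed block. With the median over spots 65 did, with the mean of log2 probe signals 59, with the sum of probe totals 57, with only the groups of the comparison 56, and with a floor 4 times lower 55. It was 46 with no scaling, 26 with quantile normalization and the scan date, 25 with no filter, 24 with median scaling and 12 with quantile normalization. It was 9 of 48 with the deposited table, 19 of the 23 above background on all 12 arrays, 7 with the total gene signal, 7 with normexp without outlying spots, 5 with the 75th percentile over all miRNAs and 0 with normexp. Signal over background limits the dim miRNAs, since a change below the floor is not seen.

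Replicate numbers share only a number across treatments. Deviations from the group mean correlated at -0.54 to -0.24 between untreated and tunicamycin arrays of the same number, and at 0.68 to 0.95 among tunicamycin arrays. The replicate block gave 1 higher and 50 lower at 12 h in WT, 1 and 27 at 24 h in WT, 0 and 2 at 12 h in KO, 1 and 1 at 24 h in KO, 30 and 3 for the 12 h difference, 13 and 1 for the 24 h difference and 10 and 44 for untreated KO, and 66 of the 69 named values kept their call. With the untreated numbers of the block crossed, 64 did, and 1 miRNA passed at 24 h in KO. The slide as a random block was not run, since slide is part of the groups and its estimated correlation was 0.

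Where no cause is given in this part, the cause was not tested. Normexp background correction gave 0 calls at 12 h in WT, 0 at 24 h in WT, 0 at 12 h in KO, 0 at 24 h in KO, 0 for the 12 h difference, 0 for the 24 h difference and 0 for untreated KO against WT. The Agilent total gene signal gave 3 at 12 h in WT, 0 at 24 h in WT, 1 for the 12 h difference, 3 for the 24 h difference, 4 for untreated KO against WT and 1 for 24 h against 12 h in KO. From the deposited table came 1 at 12 h in WT, 0 at 12 h in KO, 14 at 24 h in KO, 0 for the 12 h difference, 1 for the 24 h difference, 5 for untreated KO against WT, 1 for 24 h against 12 h in KO, 4 for list tests and 7 for responses shared by WT and KO. Quantile normalization gave 5 at 12 h in WT, 4 at 24 h in WT, 1 at 24 h in KO, 2 for the 12 h difference, 2 for the 24 h difference and 6 for untreated KO against WT. Scaled to the 75th percentile over all miRNAs, the counts were 0 at 12 h in WT, 0 at 24 h in WT, 1 at 24 h in KO, 0 for the 12 h difference, 0 for the 24 h difference and 3 for untreated KO against WT. No scaling between arrays gave 63 at 24 h in WT, 19 at 12 h in KO, 55 at 24 h in KO, 13 for the 12 h difference, 27 for untreated KO against WT, 6 for 24 h against 12 h in KO and 50 for responses shared by WT and KO. No filter on dim miRNAs gave 23 at 12 h in WT, 11 at 24 h in WT, 1 at 24 h in KO, 6 for the 12 h difference, 5 for the 24 h difference and 21 for untreated KO against WT. Testing only miRNAs well above background on all 12 arrays gave 29 at 12 h in WT, 4 at 24 h in WT, 0 at 12 h in KO, 0 at 24 h in KO, 19 for the 12 h difference, 0 for the 24 h difference and 23 for untreated KO against WT. Fits to only the groups of the comparison gave 27 at 12 h in WT, 40 at 24 h in WT, 4 at 12 h in KO, 0 at 24 h in KO, 7 for the 24 h difference and 90 for untreated KO against WT. The filters change the number of miRNAs in the adjustment, and the last setting the arrays behind the spread, by construction.

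Median scaling gave 3 at 12 h in WT, 3 at 24 h in WT, 1 at 24 h in KO, 3 for the 12 h difference, 5 for the 24 h difference and 14 for untreated KO against WT. Normexp fitted without spots of outlying local background gave 2 at 12 h in WT, 1 at 24 h in WT, 0 at 12 h in KO, 12 at 24 h in KO, 0 for the 12 h difference, 0 for the 24 h difference and 15 for untreated KO against WT. Quantile normalization with scan date as a fixed block gave 22 at 12 h in WT, 10 at 24 h in WT, 1 at 24 h in KO, 3 for the 12 h difference, 2 for the 24 h difference and 14 for untreated KO against WT. The sum of Agilent total probe signals gave 1 at 24 h in KO and 6 for the 24 h difference. With no tunicamycin arrays of replicate 2 the counts were 83 at 12 h in WT, 75 at 24 h in WT, 54 at 12 h in KO, 54 at 24 h in KO, 69 for the 12 h difference, 66 for the 24 h difference, 90 for untreated KO against WT, 23 for 24 h against 12 h in WT, 27 for 24 h against 12 h in KO, 10 for list tests and 35 for responses shared by WT and KO. With none of replicate 1 they were 96 at 12 h in WT, 89 at 24 h in WT, 61 at 12 h in KO, 82 at 24 h in KO, 74 for the 12 h difference, 71 for the 24 h difference, 90 for untreated KO against WT, 48 for 24 h against 12 h in WT and 76 for 24 h against 12 h in KO. There the spread comes from the untreated arrays alone, whose pooled SD was 0.15 and 0.13, against 0.51 to 1.23 in the tunicamycin groups. The 12 h KO count was 3 with the mean of log2 probe signals. It was 2 with a floor 4 times lower, an intensity trend, the median over spots, and scan date as a random block, which gave 23 for the 24 h difference. An estimated correlation left 0 list tests by camera.

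Leaving out each array in turn gave counts of 19 to 61 at 12 h in WT, 7 to 47 at 24 h in WT, 1 to 14 at 12 h in KO, 1 to 37 at 24 h in KO, 10 to 48 for the 12 h difference, 6 to 35 for the 24 h difference, 12 to 74 for untreated KO against WT, 0 to 0 for 24 h against 12 h in WT and 0 to 35 for 24 h against 12 h in KO. The lone remaining array is then assumed to vary like the other groups. Each highest count above 0 came without KO 24 h replicate 1. Without KO 24 h replicate 2 the counts were equally high at 12 h in WT (61), 24 h in WT (47), 12 h in KO (14), the 12 h difference (48) and untreated KO against WT (74).

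With normexp 34 of the 69 values changed sign (log2 difference in brackets). The 24 h WT values were miR-34c (0.66), miR-322 (0.20), miR-146b (0.69), miR-222 (0.31), miR-34b-5p (0.82), miR-148a (0.78), miR-143 (0.74), miR-26a (0.0347) and miR-497 (0.85). The 24 h KO values included miR-34c (-0.22). The 12 h genotype differences were miR-146b (-0.65), miR-146a (-0.40), miR-210 (-0.15), miR-34c (-0.44), miR-148a (-0.65), miR-34b-5p (-0.78), miR-129-3p (-0.55) and miR-26b (-0.0975). The 24 h genotype differences were miR-34c (-0.88), miR-34b-5p (-1.24), miR-34a (-0.17), miR-146b (-1.30), miR-210 (-0.61), miR-148a (-1.38), miR-497 (-1.51), miR-26a (-0.43) and miR-195 (-1.56). The untreated KO differences were miR-146a (0.40), miR-155 (0.37), miR-129-3p (0.45), miR-222 (0.22), miR-7a (0.44), miR-146b (0.83) and miR-29c (0.80). A few spots of extreme local background set this fit. The highest local background was 172397 on untreated KO replicate 1, with a fitted background mean of -525.4, and 13725 on WT 24 h replicate 2, with -84.7. The other arrays had fitted means from 4.44 to 19.7.

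With those spots left out 12 values changed sign or became 0. The 24 h WT values were miR-34c (0.0211), miR-34b-5p (0.19), miR-148a (0.19), miR-143 (0.16) and miR-497 (0.18). The 12 h KO values included miR-455 (0.0726). The 24 h KO values included miR-455 (0.39). The 12 h genotype differences included miR-455 (0.0726). The 24 h genotype differences included miR-455 (0.11). The untreated KO differences were miR-218 (0.00), miR-33 (0.00) and miR-24-1* (0.00).

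With the total gene signal 8 changed sign. The 12 h WT values included miR-148a (0.57). The 24 h WT values were miR-148a (1.19) and miR-143 (2.29). The 12 h genotype differences included miR-129-3p (-2.46). The untreated KO differences were miR-218 (-2.96), miR-24-1* (-2.37), miR-129-3p (1.82) and miR-7a (4.25). With the deposited table, its log2, 12 changed sign. The 12 h WT values included miR-148a (0.35). The 24 h WT values were miR-148a (0.44) and miR-143 (1.54). The 24 h KO values included let-7b (-0.44). The 12 h genotype differences were miR-148a (-0.30), miR-129-3p (-2.88) and miR-24-1* (1.86). The untreated KO differences were miR-218 (-2.62), miR-24-1* (-2.03), miR-129-3p (2.16), miR-7a (4.59) and miR-146b (0.12). Where all probes of a miRNA were above background, 0 of 1019 total gene signals exceeded 5 times the sum of probe totals. Otherwise 328 of 830 did, by up to 571.3 times. With the sum of probe totals 0 of the 69 values changed sign.

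With the 75th percentile over all miRNAs 3 changed sign. The 24 h KO values included let-7b (-0.16). The 24 h genotype differences were miR-26a (-0.0939) and miR-130a (-0.26). With no scaling 2 changed sign. The 24 h KO values were miR-34c (-0.0526) and let-7b (-0.44).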

Other observations

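The test of neighbouring genes was chosen only after the 12 h genotype difference was seen.

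miR-720, a name linked to a tRNA fragment and so to RNA quality, was the only tested miRNA of its list. It was lower in untreated KO than in WT cells, at -0.60 ± 0.15 (adjusted p = 0.0222 by limma). The median of all tested miRNAs in that comparison was -0.49, so miR-720 is hardly set apart from the general shift. It stood at 0.02 and 0.43 in the WT responses and 0.09 and 0.24 in the KO responses at 12 h and 24 h. miR-494, the only tested miRNA of the Dlk1-Dio3 cluster, did not pass in any of the 9 comparisons. miR-155, the only tested blood and endothelium marker, was at -2.68 ± 0.26 in untreated KO against WT. A probe for a murine gammaherpesvirus miRNA, mghv-miR-M1-2, was above background on 3 of 4 untreated and 8 of 8 tunicamycin arrays.

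A hypothesis that neighbouring miRNA genes share the 12 h genotype difference was tested on 72 pairs within 10000 bases, from 54 miRNAs. Their mean absolute gap was 0.51, against 0.79 for random pairs, with a one-sided permutation p of 0.0016 from 10000 permutations. This is a mean, and single pairs could go opposite ways, as miR-221 at -1.06 and miR-222 at 0.75. Shared transcription of clusters is 1 possible reason. However, many of the pairs belong to the miR-466, miR-467 and miR-669 families, whose probes are alike in sequence, so cross-hybridisation may contribute and was not tested. The median of that group also differed by 3.87 (WT) and 3.58 (KO) between the 12 h replicates, and whether this affects the gaps was not tested. Some other pairs, such as let-7f with miR-98 and miR-15a with miR-16, are of 1 family as well.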
